A study of Synechococcus sp. WH 7803 with 24 samples.

How the data were processed

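RNA of the marine cyanobacterium Synechococcus sp. WH 7803 was measured on 24 CombiMatrix oligonucleotide arrays, 1 array per culture. The 8 groups of 3 were a stressed group and its own control group for high light, cold, iron depletion and phosphate depletion. Per the labels, every condition and every control was grown in triplicate, and each array was hybridised with 4 µg of total RNA labelled directly with biotin and then fragmented. Cells of the iron and phosphate groups, controls included, had been spun for 10 min at 10000 g before the medium was changed, whereas those of the high light and cold groups had not. Group and replicate number were taken from the sample titles.

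The scanner tables deposited for each array hold 1 intensity per spot, on a linear scale and not normalized between arrays. Of the 12544 spots per array, 12000 carry intergenic probes, 340 are quality control spots, 120 are negative control spots with 8 different sequences, and 84 are empty. The lowest 27 to 29 spots of each array stand at exactly 10 and the other intensities continue smoothly from there. In all, 309 different spots stand at 10 on at least 1 array, and none of them on more than 14. The deposited intensities were taken as already background-subtracted, an assumption that was not tested. Empty spots had medians of 321 to 1295 units per array, against 428 to 1251 for the intergenic probes. Signal from spots without a probe was thus not removed, which leaves the assumption in doubt. The scanner software, the background method and the genome build are not given in the sources used here. The authors also deposited a value table on a log2 scale. Its column medians over the intergenic probes were 9.41 for all 24 columns, and over all spots they ranged from 9.37 to 9.41. Set against the log2 intensity of the same array, each column gave a correlation between 0.979 and 1.00, and over the intergenic probes the columns shared their quantiles closely, with a median absolute difference of 0.000302 or less from the quantile-normalized intensity. The scale of the value table and the absence of centring by probe were settled by that comparison, a direction does not apply to arrays with 1 colour, and the software behind the table stays unknown. The table was used only as an alternative to the scanner intensities.

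The probe names give the start and end of 1077 intergenic regions of 50 to 1432 nt (median 94 nt) and of 6000 probe positions of 21 to 35 nt each. Each position carries a probe and its reverse complement, and 6000 of the 6000 pairs were checked to be so. A unit of measurement was 1 intergenic region on 1 strand, which gave 2154 units with 1 to 70 probes each (median 4, and 1 probe for 4 units). Genes were named through the NCBI RefSeq gene table of assembly ASM6350v1. Of the 1077 regions, 1073 have both ends at a gene boundary of that table and 4 have 1 end there. The strand was settled from the sequences: 300 of 300 probes without the strand suffix that begin at the first base after a gene read rightwards start with a stop codon, so these probes carry the plus strand and detect RNA of the minus strand. A unit was called a leader when it lies upstream of 1 gene (783 units), a trailer when downstream of 1 gene (183 units), between when it has 1 gene on each side on its own strand (561 units) and opposite when both flanking genes are on the other strand (565 units). For 62 units next to an RNA gene whose strand was not known, the class was left open. A name such as cpeB-cpeA stands for the unit between 2 genes of its strand, with the gene that is read first written first. Coordinates are those in the probe names, on the single chromosome, and no build is named there. Of the 1697 flanking genes, 609 have a gene symbol, and the others keep their locus tag.

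Intensities of the intergenic probes were put on the log2 scale, quantile-normalized between the 24 arrays, and averaged over the probes of a unit. A background correction with normexp and offset 50 had been laid down for intensities not yet corrected, and it was run only as an alternative. That choice was made after the intensities had been seen. It matters for phosphate depletion, where normexp at offset 50 ended 2 of the 3 calls. A linear model with 1 mean per group was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3, so that the 8 groups shared 1 estimate of the spread per unit. Each stressed group was compared with its own controls, the effects of each pair of stresses were compared through the contrast of the 2 effects, and the 4 control groups were compared by a moderated F test. All tests were two-sided, p-values were adjusted after Benjamini and Hochberg over the 2154 units, and a unit was called at an adjusted p under 0.05. The word rose or fell is used only of called units and lists. The groups, tests, gene lists, named units and alternatives were fixed before the data were examined, except where a choice is said to have been made later. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15.

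A unit counted as above background on an array when the mean of its log2 intensities exceeded the 95th percentile of that array's negative control spots. Where no array of a group was above background, the fold was given only as a bound, beside the log2 levels or change of the fit. It set the mean of the brighter group against the mean of the dimmer group after each value of the latter under its array's 95th percentile, carried through the normalization, had been raised to it. No fold was given where that ratio was under 1 or where neither group was above background. The number of arrays limits the precision: the median standard error of a log2 change was 0.149.

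Of the 16 gene lists, 15 had at least 3 units and were tested per stress with camera in limma at a preset correlation of 0.01, with adjustment over all 60 tests. They cover iron acquisition and iron-saving electron carriers, phosphate uptake and phosphate stress, high light inducible proteins and photoprotection, heat shock and proteases, oxidative stress, cold response and RNA binding, photosystem I, photosystem II without psbA and psbD, the phycobilisome, carbon fixation and the carboxysome, cytochrome b6f with ATP synthase and NDH, ribosomal proteins and translation, nitrogen assimilation, sigma factors and transcription, and chlorophyll and tetrapyrrole synthesis. A unit belonged to a list when it lies directly upstream or downstream of a member on the same strand. The list of known noncoding RNAs had 0 units, because its matched members ffs, rnpB and ssrA border no unit of known strand. Iron stress genes such as isiA, isiB and idiA, and noncoding RNAs of the yfr family, were not matched to a symbol and were not analysed here. An estimated correlation and fry were run beside camera.

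Named units followed 1 rule per stress: among called units whose groups did not overlap, the up to 8 with the largest rise and the up to 8 with the largest fall; of each list, the up to 3 called members with the smallest adjusted p; every unit of a known noncoding RNA; and every leader of pstS, phoB, psbA, psbD or an hli gene whatever its p.

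The fitting code was tested on simulated data in which 67, 67 and 66 of the 2154 units changed 1.5-, 2- and 3-fold. It recovered 95.5% of simulated 2-fold changes in high light, 97.0% in cold, 86.6% in iron depletion and 85.1% in phosphate depletion, and 61.2%, 55.2%, 62.7% and 62.7% of 1.5-fold changes in the same order. Replicate numbers were checked for pairing through the correlation of deviations from the group means. In high light, same-numbered control and stressed arrays correlated at 0.173, 0.18 and 0.214, and each control array correlated best with its own number. A pairing by number was therefore allowed for, but it is not settled. In phosphate depletion, control array 2 correlated at 0.286 with its own number and more highly with stressed array 1. The fit with the replicate number as a block is given where it changes a call. In the other stresses not every pair passed 0.1.

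Alternatives covered the normalization (median scaling, cyclic loess), normexp at offsets 0, 1 and 50, the authors' values, a filter on dim probes that kept 3529 probes, single probes or medians as units, the arrays in the fit, the replicate block, stricter thresholds, an intensity trend with robust settings, array weights, the 412 spots in the outermost columns left out, and each array left out in turn. Slide and scan date are not given in the sources used here, so no such batch was tested.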

Results

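Transcription from the intergenic regions of Synechococcus sp. WH 7803, a marine cyanobacterium that harvests light with phycoerythrin-rich phycobilisomes, was measured on 24 arrays under 4 environmental stresses. High light cultures were moved from 30 to 280 µmol quanta per square metre and second for 1 h, and cold cultures from 23 to 10 °C for 2 h. Depleted cultures were kept without added iron for 12 h or without added phosphate for 24 h. Every stress had 3 stressed and 3 control cultures of its own, all started at 10000000 cells per ml. The question was which intergenic transcripts, among them leaders, trailers and RNA opposite to the annotated genes, respond to each stress.

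The median intergenic signal per array ranged from 428 to 1251 units of fluorescence. The 3 phosphate-stressed arrays, at 969 to 1251, were brighter than the other 21, at 428 to 806, before normalization. Between 16.6% and 45.9% of the intergenic probes of an array lay above the 95th percentile of its negative control spots. Of the 2154 units, 101 were above background on all 24 arrays, 680 on none and 1373 on some of them. Within groups, the mean correlation of an array with the other 2 lay between 0.653 and 0.909. The lowest value belonged to array 1 of the iron controls. Its brightest spot reached 9314 units, whereas the brightest spot of every other array lay between 28006 and 49059.

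In high light, 3 units beside high light inducible genes and the unit between the chaperonin genes groS and groL1 rose, and units of the phycobilisome and photosystem I operons fell. The unit hli-SynWH7803_2192, directly behind an hli gene (small chlorophyll-binding proteins with a role in photoprotection), rose 3.01-fold, from a log2 level of 10.00 ± 0.24 to 11.59 ± 0.12 (mean ± SD, n = 3 arrays each; adjusted p = 4.21e-05 in limma). Between cpeB and cpeA, which encode the β and α subunits of phycoerythrin I, the level fell by 2.01 on the log2 scale, from 11.27 ± 0.37 to 9.26 ± 0.19 (SE 0.18, adjusted p = 1.03e-06 in limma). That unit was above background on 3 of 3 control arrays and on 0 of 3 stressed arrays, so its fall was at least 3.19-fold.

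Altogether 24 of the 2154 units changed in high light, 12 up and 12 down, and 6 of them changed at least 2-fold. For all 24, the 3 stressed arrays lay beyond the 3 control arrays on the same side. Over all units, 293 (13.6%) had groups that did not overlap, where chance alone gives 10%. Of the 1527 units on the strand of a flanking gene 24 changed, against 0 of the 565 opposite units. At an unadjusted p under 0.05, limma gave 162 units in high light.

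The list of high light inducible proteins and photoprotection rose (26 units, mean log2 change 0.32, median 0.20, adjusted p = 8.52e-08, and adjusted p = 0.00198 with an estimated correlation). Of its units 3 rose, 0 fell and 23 were not called, while 8 rose and 1 fell when adjusted over the list alone. All 3 lie beside hli genes. Besides hli-SynWH7803_2192 (positions 2011989 to 2012096, plus strand, 4 probes), hli-SynWH7803_0796 (783237 to 783293, minus strand) rose from 10.22 ± 0.17 to 11.41 ± 0.17 (2.27-fold, SE of the log2 change 0.22, adjusted p = 0.00466). The last of them was the leader of an hli gene at 801224 to 801306, minus strand (log2 change 0.77, SE 0.16, adjusted p = 0.0122, above background on 1 of 3 control and 3 of 3 stressed arrays). Other hli units did not pass the test, with log2 changes of 0.63 at nth-hli, 0.37 at SynWH7803_0938-hli, 0.18 at SynWH7803_1440-hli, 0.05 upstream of the hli gene at 874155 to 874331, -0.02 at SynWH7803_2190-hli and -0.47 at rpoC2-hli. The psbA genes encode the D1 protein of photosystem II, which is damaged and replaced in strong light. None of their 4 leaders was called, but a unit averages all its probes, so a change in part of a leader is diluted. The log2 changes were 0.40 (SE 0.11, adjusted p = 0.119) at 385620 to 385791, 0.10 at 776644 to 776910, 0.05 at 1915226 to 1915608 and -0.32 at SynWH7803_0783-psbA. The first of these was called with dim probes left out (log2 change 0.69, adjusted p = 0.00257), with medians over probes (0.70, adjusted p = 0.018) and with array weights (0.42, adjusted p = 0.0441), but in no other setting. With dim probes left out nth-hli (log2 change 1.77, adjusted p = 0.0123), SynWH7803_0938-hli (1.04, adjusted p = 0.0462), SynWH7803_1440-hli (0.88, adjusted p = 0.0212) and SynWH7803_0783-psbA (-1.31, adjusted p = 0.0256) were called as well. The same setting ended the call of the hli leader at 801224 to 801306 (0.65, adjusted p = 0.139), as did a fit of only the 6 high light arrays (adjusted p = 0.185). The leaders of psbD, for the D2 protein, had log2 changes of 0.08 at 1513036 to 1513256 and 0.20 at 2065119 to 2065273, neither of them called.

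Phycobilisome units fell as a list (27 units, mean log2 change -0.38, median -0.31, adjusted p = 4.99e-14, and adjusted p = 0.000995 with an estimated correlation). Of them 8 fell, 1 rose and 18 were not called, and 15 fell and 1 rose when adjusted over the list alone. After cpeB-cpeA (493691 to 493749, plus strand, 2 probes), the largest log2 change was at cpeE-SynWH7803_0500, behind a phycoerythrin linker gene (504648 to 504767, minus strand), from 10.90 ± 0.04 to 9.38 ± 0.13, at least 2.46-fold (log2 change -1.52, adjusted p = 1.03e-06). Downstream of mpeA, the α subunit of phycoerythrin II (499472 to 499573, minus strand), the level fell 2.35-fold (log2 change -1.23, SE 0.18, adjusted p = 0.000657). The unit apcE-apcA, between the genes of the core-membrane linker and of allophycocyanin α (1853332 to 1853714, plus strand, 17 probes), fell at least 1.65-fold (log2 change -0.85, adjusted p = 0.00304). The cpeB leader (492773 to 493138, plus strand, 16 probes) fell at least 1.36-fold (log2 change -0.74, adjusted p = 0.00211), but it was not called with medians over probes (-0.41, adjusted p = 0.319). At pebB-rpcB, between a phycoerythrobilin synthesis gene and the β subunit of phycocyanin (490267 to 490419, minus strand), the log2 change was -0.85 (adjusted p = 0.0122). The 1 unit of the list that rose lies downstream of mpeU (496237 to 496349, minus strand), from 11.01 ± 0.15 to 11.79 ± 0.07 (1.72-fold, adjusted p = 0.00287).

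**Figure D1:**
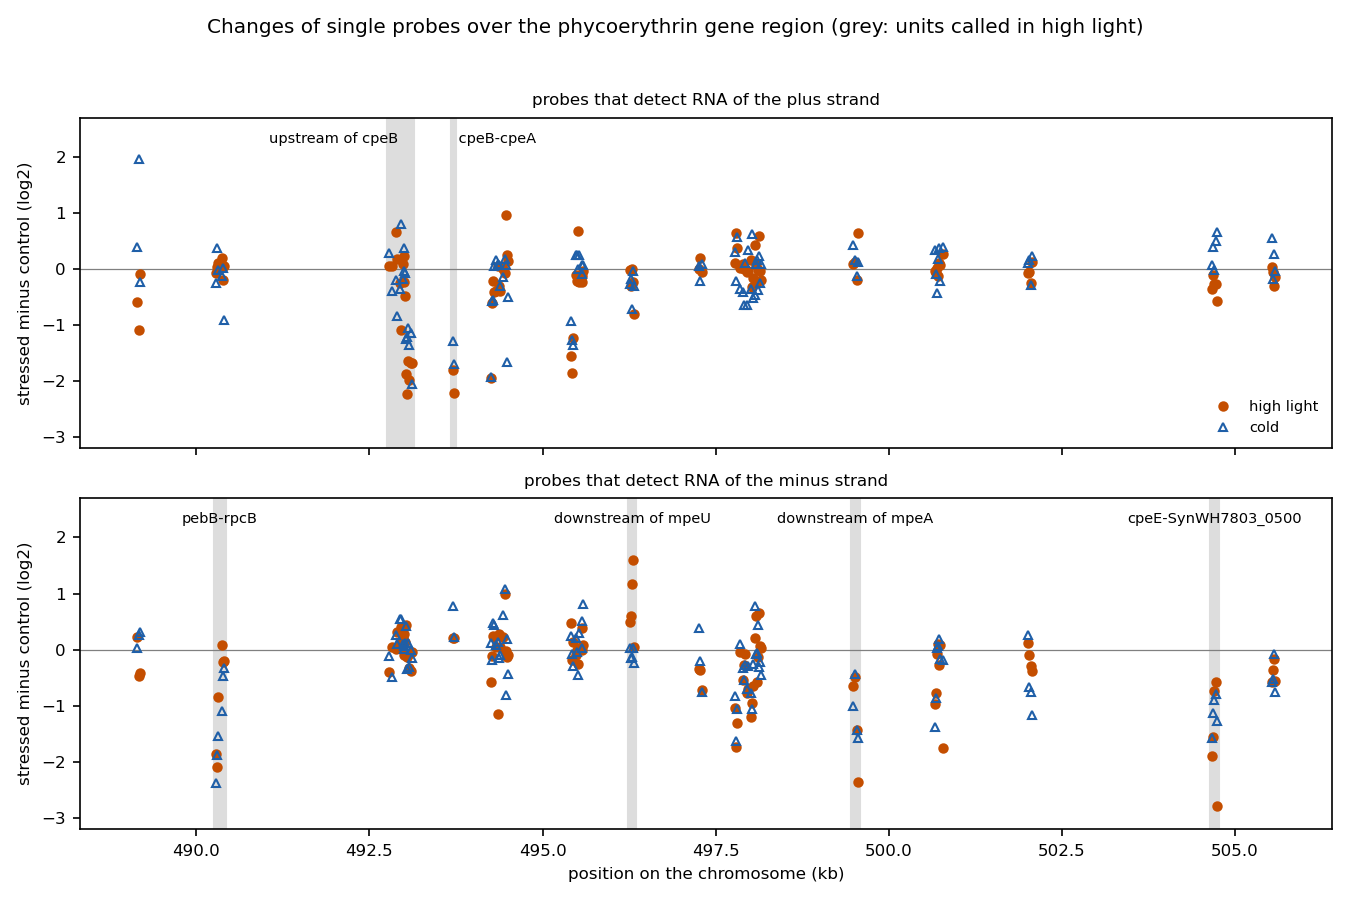
Log2 change of each of 202 probes between 489.1 and 505.6 kb (x axis, position in the coordinates of the probe names). The upper panel shows probes that detect RNA of the plus strand and the lower panel those of the minus strand, with high light as filled circles and cold as open triangles. Grey bands mark the named units called in high light, and units without a name carry no band whether called or not. Probes at cpeB-cpeA, at cpeE-SynWH7803_0500 and downstream of mpeA lie below 0 in both stresses, and those downstream of mpeU lie above 0 in high light.

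Photosystem I units fell as well (15 units, mean log2 change -0.34, median -0.32, adjusted p = 3.05e-09, and adjusted p = 0.00457 with an estimated correlation). Of these 3 fell, 0 rose and 12 were not called, and 8 fell when adjusted over the list alone. The unit downstream of psaB, a reaction centre gene (419465 to 419559, plus strand), went from 10.91 ± 0.20 to 10.00 ± 0.17, a fall of 1.88-fold (adjusted p = 0.000663). The others were psaD-trpE (470991 to 471072, minus strand; log2 change -0.74, at least 1.32-fold, adjusted p = 0.0122) and the unit downstream of psaK (1115976 to 1116032, minus strand; log2 change -0.53, adjusted p = 0.0295). In the photosystem II list (23 units), 1 unit fell, psbU-nadB (2027723 to 2027778, plus strand; log2 change -0.59, adjusted p = 0.0339), behind a gene of the oxygen-evolving complex. The list was not called (adjusted p = 0.698).

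Of the 22 heat shock and protease units, 1 rose. It was groS-groL1, between the genes of GroES and GroEL (1827939 to 1827994, minus strand), which went from 10.05 ± 0.09 to 11.08 ± 0.16 (2.04-fold, SE 0.18, adjusted p = 0.00287). The list as a whole was not called (adjusted p = 0.129). Other rises were at SynWH7803_0846-mtnA (811608 to 811699; log2 change 0.99, adjusted p = 0.00178), where mtnA belongs to methionine salvage, and upstream of SynWH7803_1000 (920604 to 920809; 0.92, at least 1.46-fold, adjusted p = 0.000535). Rises were also called at hisF-SynWH7803_1773 (1625907 to 1625966; 0.85, at least 1.37-fold, adjusted p = 0.00287), behind a histidine synthesis gene, and at clpA-gldA (1412974 to 1413023; 0.81, adjusted p = 0.00331), behind the gene of a Clp protease ATPase. The other 10 lists had adjusted p from 0.439 to 0.918 in high light. The leaders of phoB, pstSI and pstSII, genes of the phosphate response, had log2 changes of 0.14, 0.16 and -0.05.

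With the replicate number as a block, which pairs the high light arrays, 22 units were called, 18 of them shared. The block ended the calls at psbU-nadB (blocked adjusted p = 0.107), pebB-rpcB (0.059), psaD-trpE (0.0574) and downstream of psaK (0.0574). Medians over probes also ended the calls at psaD-trpE (-0.60, adjusted p = 0.141), psbU-nadB and downstream of psaK (0.0578 for both). Normexp at offsets 0 and 1 ended the last 2 (0.0644 to 0.0778), and the fit of only the 6 high light arrays ended that downstream of psaK (0.185). With median scaling 13 units were called, and groS-groL1, clpA-gldA, pebB-rpcB, psbU-nadB and the units downstream of mpeU and psaK were not among them (adjusted p from 0.0902 to 0.426). Without control array 1 the calls at psbU-nadB (adjusted p = 0.13), psaD-trpE (0.0866), pebB-rpcB (0.0793) and downstream of psaK (0.189) ended. Without stressed array 3 the same 4 ended (0.0856 to 0.0894). The call at psbU-nadB also ended without control array 2 (0.0922), control array 3 (0.115), stressed array 1 (0.184) or stressed array 2 (0.088). That downstream of psaK ended without control array 2 (0.0752) or stressed array 2 (0.193), and that of the hli leader without control array 2 (0.0922), control array 3 (0.0862) or stressed array 1 (0.113).

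**Figure D2:**
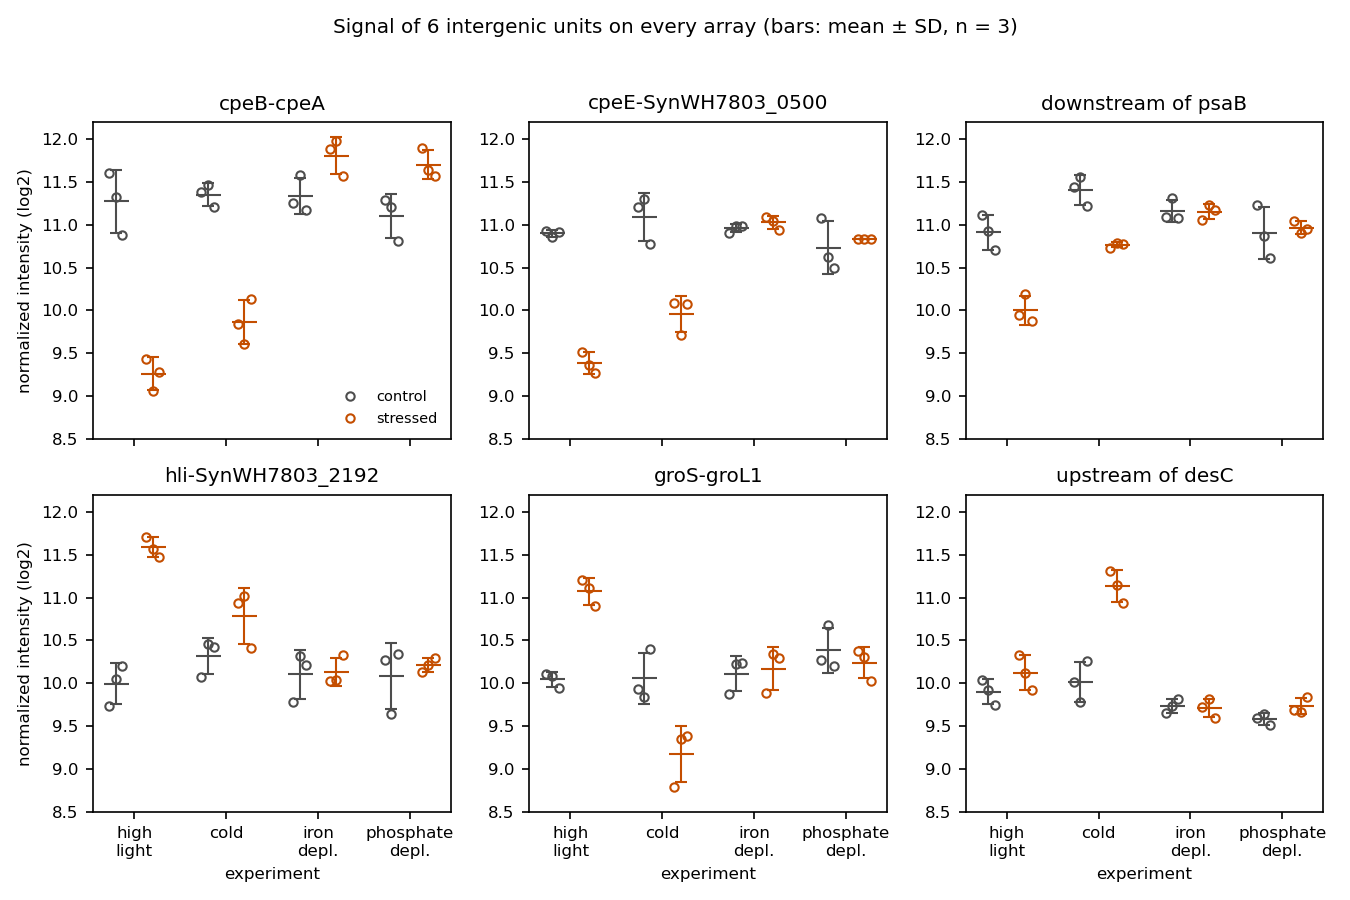
Normalized log2 level (y axis) of 6 units on each array, with the mean and SD of every group of 3, for the control and stressed arrays of the 4 stresses (x axis). The units are cpeB-cpeA, cpeE-SynWH7803_0500, the one downstream of psaB, hli-SynWH7803_2192, groS-groL1 and the desC leader. The unit cpeB-cpeA lies at 11.27 in the high light controls and at 9.26 in high light, and the desC leader at 10.01 in the cold controls and at 11.13 in cold.

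In cold, 32 of 36 changes were falls, 16 of them at units of the phycobilisome, the photosystems and the carbon-fixing operon, while the leader of the fatty acid desaturase gene desC rose. The desC leader (2249100 to 2249292, plus strand, 8 probes) went from 10.01 ± 0.24 to 11.13 ± 0.19 (2.17-fold, n = 3 arrays each, adjusted p = 3.05e-05 in limma) and was above background on 2 of 3 control and 3 of 3 stressed arrays. At cpeB-cpeA the level fell by 1.49 on the log2 scale, from 11.35 ± 0.13 to 9.86 ± 0.26 (2.81-fold lower, SE 0.18, adjusted p = 5.39e-05 in limma), with 3 of 3 control and 1 of 3 stressed arrays above background.

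Of the 2154 units 36 changed in cold, 4 up and 32 down (88.9% falls), and 6 changed at least 2-fold. The groups of 35 of them did not overlap, as was the case for 318 units (14.8%) over all, where chance gives 10%. Of the units on the strand of a flanking gene, 32 of 1527 changed, against 4 of 565 opposite units. At an unadjusted p under 0.05, limma gave 245 units. Median scaling called 12 units, 3 up and 9 down.

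The phycobilisome list fell in cold (27 units, mean log2 change -0.38, median -0.30, adjusted p = 1.17e-11, and adjusted p = 0.00158 with an estimated correlation). Of its units 8 fell, 0 rose and 19 were not called, and 13 fell when adjusted over the list alone. The unit pebB-rpcB fell 2.43-fold (log2 change -1.28, SE 0.18, adjusted p = 0.000163) and cpeE-SynWH7803_0500 went from 11.09 ± 0.28 to 9.96 ± 0.21 (2.2-fold lower, adjusted p = 5.39e-05). The unit downstream of mpeA fell 2.16-fold (log2 change -1.11, adjusted p = 0.00108) and apcE-apcA fell 1.89-fold (log2 change -0.91, adjusted p = 0.00108). Each of the last 3 was above background on 3 of 3 control arrays and on 1 of 3 stressed arrays. On cold-stressed array 1 the background threshold was 1409 units, against 710 to 886 on the cold controls, and 19.5% of its intergenic probes exceeded it. Lower counts above background on the cold-stressed arrays, at every unit given for cold, may thus owe part to that threshold.

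Units of photosystem II fell as a list (23 units, mean log2 change -0.21, adjusted p = 0.000346, and adjusted p = 0.0249 with an estimated correlation), with 2 falling and 21 not called, and 5 falling when adjusted over the list alone. These were psbU-nadB (at least 1.46-fold, log2 change -0.98, adjusted p = 0.000244) and psbY-SynWH7803_1382 (1270444 to 1270519, minus strand; log2 change -0.58, adjusted p = 0.0037), the second not above background on any of the 6 arrays. Photosystem I units fell at the preset correlation (15 units, mean log2 change -0.26, adjusted p = 0.00208), but not with an estimated one (adjusted p = 0.122 with an estimated correlation). Of these 3 fell and 12 were not called, and 5 fell and 1 rose when adjusted over the list alone. The 3 were psaD-trpE (log2 change -0.94, at least 1.13-fold, adjusted p = 0.00103), the unit downstream of psaK (-0.75, adjusted p = 0.00103) and the unit downstream of psaB (-0.64, adjusted p = 0.0142).

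The carbon fixation and carboxysome list fell (11 units, mean log2 change -0.33, adjusted p = 0.00251), a call that was lost with an estimated correlation (adjusted p = 0.182 with an estimated correlation). Its 3 falling units are neighbours in the operon that encodes a carboxysome shell protein and the 2 subunits of Rubisco. Another 8 units were not called, and 4 fell when adjusted over the list alone. They were csoS1/ccmK1-rbcL/cbbL (674486 to 674559, plus strand; log2 change -1.18, SE 0.29, adjusted p = 0.0404, groups overlapping), rbcL/cbbL-rbcS/cbbS (675973 to 676034; -0.97, SE 0.19, adjusted p = 0.00683) and rbcS/cbbS-csoS2 (676374 to 676477; -0.91, SE 0.21, adjusted p = 0.0294). All 3 were above background on 2 of 3 control arrays and on 0 of 3 stressed arrays, which bounds the falls at 1.42-fold, 1.30-fold and 1.04-fold. The list of iron acquisition and iron-saving electron carriers fell too (11 units, mean log2 change -0.21, adjusted p = 0.00711, and adjusted p = 0.122 with an estimated correlation), with 2 falling over all units and over the list alone, and 9 not called. Both lie at genes of photosynthetic electron carriers. The unit petF-SynWH7803_1978 (1811667 to 1811770, minus strand; log2 change -0.79, adjusted p = 0.00177) lies behind a ferredoxin gene. The unit petE-petJ (735907 to 736042, minus strand; -0.59, adjusted p = 0.0125) lies between the genes of plastocyanin and cytochrome c6.

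Among the other lists, heat shock and proteases had 1 unit that fell, groS-groL1 (log2 change -0.89, at least 1.06-fold, adjusted p = 0.0109). Ribosomal proteins and translation had 1 that rose, rplI-dnaB (2250585 to 2250684, plus strand; 0.73, SE 0.09, adjusted p = 5.39e-05), and 1 that fell, SynWH7803_1330-rpsB (1227053 to 1227188; -0.69, adjusted p = 0.00103). The cold response list had 1 that rose, the desC leader. Of the nitrogen list glnN-SynWH7803_1457 (log2 change -0.53, adjusted p = 0.036), behind a glutamine synthetase gene and not above background on any array of either group, fell. Of the phosphate list the unit downstream of ppa, a pyrophosphatase gene, fell (608120 to 608216; -0.49, adjusted p = 0.028, above background on 1 of 3 control and 0 of 3 stressed arrays). The lists themselves were not called, heat shock at adjusted p = 0.801, ribosomal proteins at 0.698, cold response at 0.503, nitrogen assimilation at 0.0597 (0.0195 with fry) and phosphate at 0.777. The remaining lists had adjusted p of 0.171 (cytochrome b6f, ATP synthase and NDH), 0.252 (oxidative stress), 0.586 (chlorophyll synthesis, and high light inducible proteins) and 0.917 (sigma factors). Opposite strands also changed in cold. Between SynWH7803_0948 and dcd (887419 to 887771, minus strand, 16 probes), the signal opposite to both genes went from 9.78 ± 0.10 to 10.52 ± 0.09 and from 0 of 3 to 3 of 3 arrays above background, a rise of at least 1.60-fold (adjusted p = 2.6e-05). Between SynWH7803_2511 and SynWH7803_2512 (2342014 to 2342096, minus strand) it rose 1.33-fold (log2 change 0.41, adjusted p = 0.0435). The other 2 called opposite units, named after their values were seen, fell: the opposite strand between SynWH7803_0921 and SynWH7803_0922 by 0.65 on the log2 scale (adjusted p = 0.0134) and the opposite strand between SynWH7803_2237 and SynWH7803_2238 by 0.56 (adjusted p = 0.0211). The leaders of psbA, psbD, phoB and the hli genes were not called in cold, with log2 changes from -0.39 at SynWH7803_0783-psbA to 0.44 at nth-hli.

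When only the 6 cold arrays entered the fit, 1 unit was called, cpeB-cpeA, and the other 22 named calls ended (adjusted p from 0.0675 to 0.408). Median scaling ended 11 of the named calls (adjusted p from 0.055 to 0.426), among them petF-SynWH7803_1978, petE-petJ, groS-groL1, SynWH7803_1330-rpsB and the units downstream of psaB and psaK. Leaving out 1 cold array ended 8 named calls without control array 1 (adjusted p from 0.0507 to 0.166), 7 without control array 2 (0.0605 to 0.212) and 3 without control array 3 (0.0574 to 0.103). It ended 5 without stressed array 1 (0.0575 to 0.187), 4 without stressed array 2 (0.0964 to 0.144) and 4 without stressed array 3 (0.0578 to 0.165). These came from 9 units, the 3 of the Rubisco operon, groS-groL1, petE-petJ, glnN-SynWH7803_1457, the units downstream of psaB and ppa, and the one opposite to SynWH7803_2511 and SynWH7803_2512. The last of these and csoS1/ccmK1-rbcL/cbbL also lost their calls when single arrays of other stresses were left out (adjusted p from 0.0501 to 0.0603). With medians over probes petE-petJ stood at -0.20 (adjusted p = 0.605), rbcS/cbbS-csoS2 at -0.52 (0.353) and glnN-SynWH7803_1457 at -0.41 (0.308). With dim probes left out psbY-SynWH7803_1382 stood at -0.32 (0.407), and the unit opposite to SynWH7803_2511 and SynWH7803_2512 at 0.23 (0.29).

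**Figure D3:**
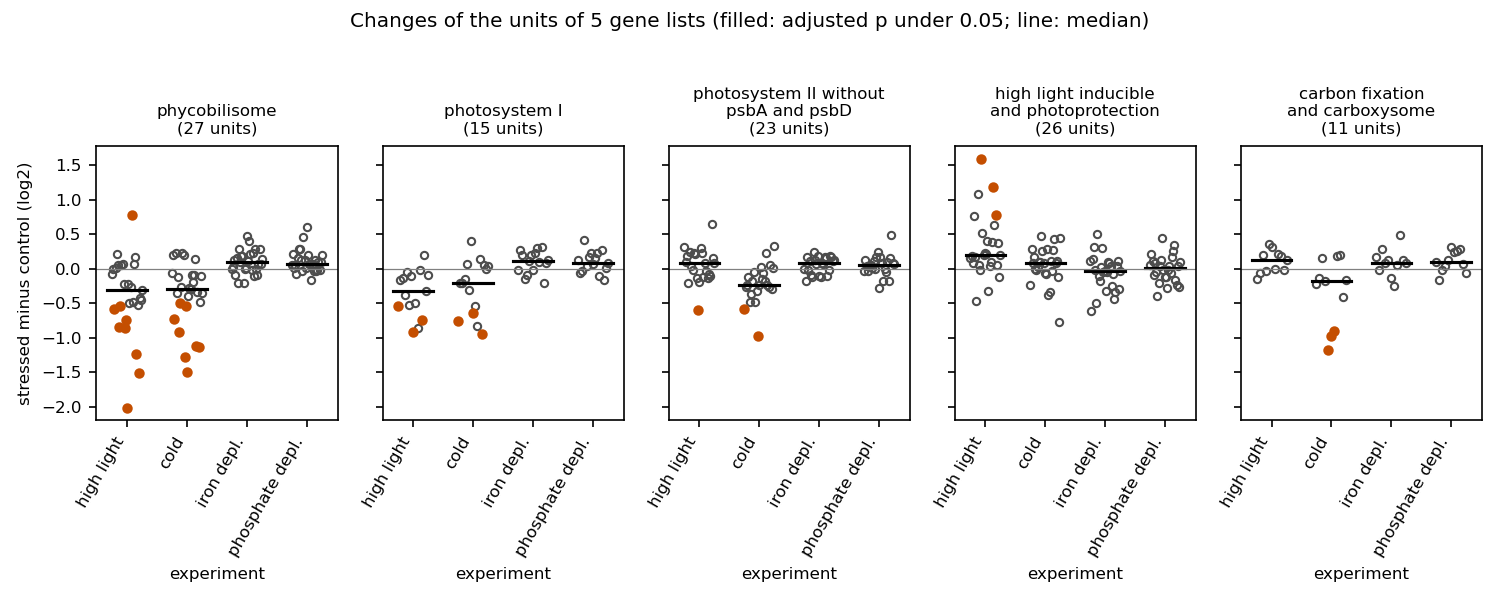
Log2 change of every unit (points, y axis) in 5 gene lists, with the list median as a line, for each of the 4 stresses (x axis). The phycobilisome median was -0.31 in high light, -0.30 in cold and 0.08 in phosphate depletion, and the high light inducible list had a median of 0.20 in high light and 0.08 in cold.

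High light and cold shared many of their falls. All 12 units that fell in high light also fell in cold, where 0.178 would be shared by independent lists of 12 and 32 among 2154 units. Units of 1 operon are not independent, and both calls use the same spread per unit, but the 2 stresses share no control arrays. With the replicate block 7 of the 12 fell in both, and with median scaling 5. Only cpeB-cpeA was called in cold when the fit held the 6 cold arrays alone. They include the phycobilisome units cpeB-cpeA, cpeE-SynWH7803_0500, apcE-apcA and pebB-rpcB, the cpeB leader and the unit downstream of mpeA, the 3 photosystem I units and psbU-nadB. Of the rises 0 were shared, and 2 units rose in high light and fell in cold, groS-groL1 and clpA-gldA. Across all units, which are not independent replicates, the 2 sets of log2 changes correlated at 0.174, no more than cold did with iron (0.187) or phosphate depletion (0.175), or these 2 with each other (0.291). High light correlated at 0.0347 with iron and at -0.0165 with phosphate depletion.

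Iron depletion for 12 h gave no called unit or list. At groS-groL1 and cpeB-cpeA, named for the other stresses, and at all iron units, no change passed the test. In limma 0 of the 2154 units were called, while 206 had an unadjusted p under 0.05 and 309 (14.3%) had groups that did not overlap, where chance gives 10%. The counts were also 0 with array weights and with only the 6 arrays of this comparison, and 1 with median scaling or with an intensity trend and robust settings. Without stressed array 1 limma called 4 units. The smallest adjusted p, 0.0778, belonged to the unit upstream of SynWH7803_1011 (927392 to 927826, minus strand), named after its values were seen, with a log2 change of 0.89 (SE 0.17). Among the 11 units of the iron list, sufB-sufC, between genes of iron-sulfur cluster assembly, had a log2 change of -0.58 (adjusted p = 0.509) and petE-petJ one of 0.19. The list was not called (adjusted p = 0.917). The other 14 lists had adjusted p of 0.124 (phycobilisome), 0.224 (ribosomal proteins), 0.279 (photosystem I) and 0.377 to 0.917 (the rest). The leaders of psbA, psbD, phoB, pstSI, pstSII and the hli genes had log2 changes from -0.62 at SynWH7803_1440-hli to 0.15 at the psbD leader of 1513036 to 1513256, none of them called.

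After 24 h without phosphate, the unit pstSII-ptrA, between a gene of a phosphate-binding protein and the gene of the regulator PtrA, rose. It lies at 961456 to 961588 on the plus strand, has 6 probes and went from 10.19 ± 0.23 to 10.86 ± 0.02 (1.59-fold, SE of the log2 change 0.13, n = 3 arrays each, adjusted p = 0.0485 in limma), with 2 of 3 control and 3 of 3 stressed arrays above background. In all 3 units changed, 2 up and 1 down, at groups that did not overlap, while 178 had an unadjusted p under 0.05 and 395 (18.3%) had groups that did not overlap, where chance gives 10%. The second rise was at SynWH7803_0112-SynWH7803_0111 (117054 to 117739, minus strand, 31 probes), from 9.18 ± 0.06 to 9.63 ± 0.03 (SE 0.08, adjusted p = 0.015), with 0 of 3 control and 2 of 3 stressed arrays above background. On stressed array 1 the median of the empty spots, 1295 units, itself exceeded the background threshold of 1176. Counts above background on the stressed arrays are therefore weak evidence of RNA. The fall was at SynWH7803_1230-corA (1120384 to 1120463, minus strand, 3 probes), next to a magnesium transporter gene, from 8.20 ± 0.19 to 5.36 ± 0.52 (SE 0.49, adjusted p = 0.015). This unit was not above background on any of the 6 arrays, so its change lies under the background level.

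Of the 18 units of the phosphate list 1 rose, pstSII-ptrA, both over all units and adjusted over the list alone, and 17 were not called. The list itself stayed above the threshold (mean log2 change 0.15, adjusted p = 0.0562, and adjusted p = 0.122 with an estimated correlation), whereas fry, which tests for any change rather than against the other units, gave it an adjusted p of 0.0195. The leaders of pstSI, pstSII and phoB, the genes of phosphate-binding proteins and of the response regulator, had log2 changes of -0.03, 0.16 and -0.14, none of them called. A change in only part of a leader would be diluted there too, because a unit averages all its probes. The phycobilisome list was called upward (27 units, mean log2 change 0.11, adjusted p = 0.039), with 0 of its units called over all or over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.305 with an estimated correlation) and with fry (adjusted p = 0.174). The other 13 lists had adjusted p from 0.255 (photosystem I) to 0.952 (ribosomal proteins). Normexp ended the calls of SynWH7803_1230-corA and pstSII-ptrA (adjusted p from 0.142 to 0.556 over offsets 0, 1 and 50). The log2 change of SynWH7803_1230-corA shrank from -2.84 to -1.29, -1.27 and -0.73 there, and that of pstSII-ptrA to 0.38 with medians over probes (adjusted p = 0.594). Median scaling ended those of pstSII-ptrA and SynWH7803_0112-SynWH7803_0111 (0.0693 for both). These 2 calls also ended with dim probes left out (0.0641 and 0.0755), with medians over probes (0.594 and 0.0624) and with only the 6 phosphate arrays (0.278 for both). An intensity trend with robust settings ended all 3 (0.0511 to 0.0533). Without control array 1 (adjusted p = 0.0668), control array 2 (0.105 to 0.17) or stressed array 2 (0.121 to 0.29) of the phosphate groups, all 3 calls ended. Of them 2 ended without stressed array 1 (0.0818 and 0.159), and without stressed array 3 the 3 ended (0.0698 to 0.122) while 1 other unit was called. The call at pstSII-ptrA held in 11 of 40 other settings and ended when any of 13 arrays of other stresses was left out (0.0504 to 0.077).

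Differences between stresses were tested directly. High light and cold differed at 11 units, 9 of them higher and 2 lower in high light, with the largest difference at groS-groL1 (1.92 on the log2 scale, SE 0.26, adjusted p = 0.000717). High light differed from iron depletion at 12 units (5 higher, 7 lower). From phosphate depletion it differed at 18 (8 higher, 10 lower), led by cpeB-cpeA (-2.61, SE 0.26, adjusted p = 5.91e-06 in limma). With the replicate block, high light differed at 7 units from cold, 12 from iron and 12 from phosphate depletion. Leaving out 1 array took the counts without the block as low as 5, 3 and 6, in the same order. Cold differed from iron depletion at 13 units (3 higher, 10 lower) and from phosphate depletion at 16 (4 higher, 12 lower). Between iron and phosphate depletion limma called 0 units, with 117 at an unadjusted p under 0.05, and median scaling called 1. The unadjusted numbers for the other 5 pairs lay between 160 and 191.

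The 4 control groups, of which the iron and phosphate ones had been centrifuged, differed at 1 unit, nirA-SynWH7803_2493 (2322047 to 2322302, plus strand), behind the nitrite reductase gene. Its level was 9.24 ± 0.14 in the high light controls, 9.84 ± 0.45 in the cold controls, 10.41 ± 0.10 in the iron controls and 10.42 ± 0.10 in the phosphate controls (adjusted p = 0.00139 for the moderated F test in limma). At an unadjusted p under 0.05 there were 173 units, and with median scaling limma called 0.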

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

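The counts of calls in the 10 splits of each single stress, the splits that part the numbered pairs of high light and the replicate block for differences between stresses were chosen as tests only after the results had been seen.

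Effects differed between stresses at named units, as tested through the contrast of the 2 effects in limma. Of 300 such differences at named units, 59 passed the threshold, at 28 units. Many of the named units had been picked for a call on the same arrays, which raises that number. Given here are all the passing differences between high light and cold and, for every other unit, the largest. High light minus cold was 1.92 at groS-groL1 and 1.43 at clpA-gldA, units that rose in one stress and fell in the other. It was 1.29 at rbcL/cbbL-rbcS/cbbS, 0.98 at petF-SynWH7803_1978 and 0.90 at psbY-SynWH7803_1382, units called only in cold. It was 0.87 downstream of mpeU, -0.90 upstream of desC and -0.61 opposite to SynWH7803_0948 and dcd. Adjusted p for these 8 ranged from 0.000717 to 0.0439. With the replicate block, which pairs the high light arrays, the calls at rbcL/cbbL-rbcS/cbbS (adjusted p = 0.0994), petF-SynWH7803_1978 (0.0705), upstream of desC (0.0705) and opposite to SynWH7803_0948 and dcd (0.0718) ended.

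High light minus iron depletion was 1.56 at hli-SynWH7803_2192, 1.11 upstream of the hli gene at 801224 to 801306 and -1.22 downstream of mpeA (adjusted p from 0.00798 to 0.0287). High light minus phosphate depletion was -2.61 at cpeB-cpeA, -1.62 at cpeE-SynWH7803_0500, -0.98 downstream of psaB and -0.76 upstream of cpeB. In the other direction it was 1.25 upstream of SynWH7803_1000, 1.15 at hisF-SynWH7803_1773, 1.10 at SynWH7803_0846-mtnA, 0.94 downstream of mpeU and 0.68 upstream of the psbA gene at 385620 to 385791. At SynWH7803_0112-SynWH7803_0111, which rose in phosphate depletion, it was -0.49. Adjusted p for this pair ranged from 5.91e-06 to 0.0484, the highest of them at the psbA leader, whose change in high light alone was not called. The block ended the calls upstream of this psbA (adjusted p = 0.18) and of cpeB (0.0519), at SynWH7803_0846-mtnA (0.0541) and at SynWH7803_0112-SynWH7803_0111 (0.124). The 3 differences from iron depletion kept theirs (0.00203 to 0.0295).

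Cold minus iron depletion was -1.26 at psaD-trpE, -1.20 at apcE-apcA, -0.78 at petE-petJ, -0.76 at SynWH7803_1330-rpsB and 1.14 upstream of desC (adjusted p from 0.00277 to 0.0395). Cold minus phosphate depletion was -1.42 at pebB-rpcB, -1.22 at psbU-nadB and -0.87 downstream of psaK. It was 0.91 at rplI-dnaB and 0.75 opposite to SynWH7803_0948 and dcd (adjusted p from 0.000956 to 0.011).

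Over all units the pairs of stresses differed at 11 (high light and cold), 12 (high light and iron), 18 (high light and phosphate), 13 (cold and iron) and 16 units (cold and phosphate). These counts were set against 100 drawn splits of the same arrays, in a model without the pairing of the high light arrays. With the real one included, 3 splits had as many calls for high light and cold and 3 for high light and iron. There was 1 for high light and phosphate, and there were 4 for cold and phosphate. The splits break up the groups of both stresses, so they bear on an effect of either stress, not on a difference between the 2 effects. The highest other split gave 18 calls for high light and cold, 14 for high light and iron, 10 for high light and phosphate and 26 for cold and phosphate. For cold and iron depletion 5 splits had as many, which leaves chance open even there, with 13 real calls and 16 in the highest other split. In these 5 pairs, every other split with as many calls kept the real grouping of 1 of the 2 stresses. Among the 80 splits that part all 3 numbered pairs of high light, 5 had as many calls for high light and cold (6.25%), the real one included. By that share chance cannot be excluded, but 3 of the 5 kept 1 real grouping and 0 had neither grouping real. There 11 calls stand against 41 in the split with both real groupings and the direction of 1 turned, where shared falls add up, and at most 18 in the rest. For high light and iron (12 calls, at most 14 elsewhere) the share with as many was 3.75%. For high light and phosphate (18 calls, at most 10 elsewhere) it was 1.25%. Both shares bear on an effect of either stress, not on a difference between the 2 effects. With the replicate block these 3 pairs differed at 7, 12 and 12 units, of which 6, 8 and 11 were shared. For iron and phosphate depletion, with 0 real calls and at most 1 in another split, every split has as many by construction, so these splits decide nothing. Chance cannot be excluded for the 1 unit that differed among the control groups (3 in the highest other split). Nor can it for the 9 called lists (12 in the highest other split).

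For a single stress, 3 arrays against 3 make 10 splits, too few for a share under 0.05. High light gave 24 calls and at most 1 in another split, cold 36 and at most 2, iron depletion 0 and at most 0, and phosphate depletion 3 and at most 0. Among the 4 high light splits that part all 3 numbered pairs, the highest other gave 0 calls, while the remaining 6 splits each put both arrays of at least 1 pair on the same side.

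Empty spots, which carry no probe and enter no comparison, gave signal above the control spots. On 19 of the 24 arrays their median signal exceeded that of the negative control spots. The median of the empty spots was 985 to 1295 on the 3 phosphate-stressed arrays.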

How the results depend on the processing

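The alternatives with normexp at offset 50, with the replicate block for differences between stresses, with the outermost columns left out, and with single arrays left out for the control groups and the lists were chosen as tests after the data had been seen. Among named units, 45 of 108 pairs of unit and stress were called. Over 1798 fits of these 45 under other settings 1575 kept the call, 223 lost it and 0 reversed, and 7 of 2504 fits of uncalled pairs gained one. Many of these settings leave the values of a comparison the same or nearly so, such as the authors' values or an array of another stress left out. The share of calls kept therefore overstates how firm the calls are. The authors' values, quantile-normalized too, gave the same counts of 24, 36, 0 and 3 calls for high light, cold, iron and phosphate. Without the outermost columns there were 24, 44, 0 and 3. With median scaling the counts were 13 (6 up, 7 down), 12 (3 up, 9 down), 1 and 1, with 3 units for high light against cold, 7 for cold against iron, 1 for iron against phosphate, 0 among the controls and 15 lists, the 9 called ones included. Under median scaling the median change over all units was 0.107 in iron depletion, against 0.00661 without it, and at most 0.0564 in size elsewhere. Cyclic loess gave 61 units in cold. With normexp at offset 0, at offset 1 and at offset 50 phosphate depletion had 1 call, and at offsets 0 and 1 high light differed from phosphate depletion at 10 units. Leaving out dim probes, which tests 1546 units, gave 69 calls in cold and 1 in iron depletion, and differences at 20 units (high light and cold), 24 (high light and iron), 27 (cold and iron) and 31 (cold and phosphate). Testing single probes gave 57, 147, 1 and 8 calls. With only the 6 arrays of a comparison, cold had 1 call, against 23 in high light (19 shared), 0 in iron depletion and 3 in phosphate depletion, of which 1 was shared. The replicate block gave 22, 38, 1 and 1 calls and 8 lists, and 7 units for high light against cold (6 shared), 12 for high light against iron, 12 for high light against phosphate, 14 for cold against iron and 15 for cold against phosphate. In high light it ended the 4 named calls given in the report and no other named call or list. In cold each control array correlated best with the stressed array of its own number (0.0303, 0.0847 and 0.17), so a pairing there cannot be excluded. The block ended the cold calls downstream of ppa (adjusted p = 0.0506), at glnN-SynWH7803_1457 (0.0856) and opposite to SynWH7803_2511 and SynWH7803_2512 (0.0839). In iron (0.0454, 0.00164 and 0.0466) and phosphate depletion (-0.24, 0.286 and 0.0567) not every control array correlated best with its number, and the block ended the phosphate calls at pstSII-ptrA (0.148) and SynWH7803_0112-SynWH7803_0111 (0.119). A minimum of 2-fold left 6, 6 and 1 calls in high light, cold and phosphate depletion and an adjusted p under 0.01 left 14, 17 and 0, by construction. An intensity trend with robust settings gave 1 call in iron and 0 in phosphate depletion, and array weights gave 40 in high light and 7 in phosphate depletion. With an estimated correlation 5 lists were called, and fry called 10. Where construction does not show it, the cause was not tested. With 1 array left out, the calls ranged from 17 to 29 in high light, from 22 (without cold control 2) to 58 (without iron control 1) in cold, from 0 to 4 (without iron stressed 1) in iron depletion and from 0 (without phosphate control 1, control 2 or stressed 2, and 1 without stressed 1 or 3) to 4 in phosphate depletion. Differences ranged from 5 to 16 for high light and cold (5 without cold stressed 1, 6 without high light control 3 or stressed 2, 7 without high light stressed 1 or cold control 2). For high light and iron they ranged from 3 to 16 (3 without high light control 2, 4 without high light stressed 1, 5 without high light control 1, 6 without iron control 1 or stressed 2, 7 without iron control 3). For high light and phosphate they ranged from 6 to 22 (6 without high light or phosphate control 2, 7 without phosphate stressed 2, 8 without either stressed array 1, 10 without high light stressed 3 or phosphate control 1, 11 without high light control 1). For cold and iron they ranged from 7 (without cold control 1, and 8 without iron control 1) to 20 (without cold control 3), and for cold and phosphate from 11 to 22. For iron and phosphate they ranged from 0 to 3 (3 without iron stressed 1, 1 without high light stressed 2 or 3, iron control 2 or phosphate stressed 3). The control groups differed at 1 or 2 units (2 without cold control 3 or cold stressed 1), and 8 to 12 lists were called. Signal over background limits the rest: 680 units were above background on no array. The planned block for slide or scan date was not run, because neither is given in the sources used here.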

Other observations

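The tests of the iron counts (without the weak array, recovery of simulated changes, spread within groups), of base composition, of the other strand and of a shared response to excess light energy were chosen only after those results had been seen. The bounds for base composition (from 50% to 20%) and for the other strand were also lowered at that stage.

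Some units were above background on all 24 arrays with little variation between them. The 4 given here were chosen after their values were seen. The unit downstream of purK, a purine synthesis gene (1100200 to 1100394, plus strand, 8 probes), had a mean log2 level of 13.15 with an SD of 0.16 over the 24 arrays. On the strand opposite to both flanking genes, the unit between the ATP synthase genes atpA and atpD (1845763 to 1845825, 2 probes) stood at 13.44 with an SD of 0.13, and that between psaL and psaI (424681 to 424741, 2 probes) at 12.43 with an SD of 0.16. The opposite strand between SynWH7803_2237 and SynWH7803_2238 (2062102 to 2062350, minus strand, 13 probes) stood at 12.25 with an SD of 0.23 and fell in cold (log2 change -0.56, adjusted p = 0.0211). The other 3 were not called in any of the 4 stresses.

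Within the cpeB leader, also chosen after its values were seen, the fall in high light was uneven. Of its 16 probes, 7 had log2 changes under -1 in high light, and 6 of these were among the 7 nearest to the cpeB start, with middles from 493019 to 493118. The median change of these 7 probes was -1.68 in high light and -1.21 in cold, against 0.06 and -0.18 for the other 9. No test was run on this split.

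The 12 units that fell in high light had a median log2 change of -0.93 in cold. Random sets of 12 units matched on brightness and spread gave a 2.5th percentile of -0.14, or -0.13 when matched on GC share too, and 0% of 10000 sets were as low. Leaving out any 1 of the 6 cold arrays left the median between -0.84 and -1.01. These values argue against brightness, GC share or a single cold array as the whole cause. A probe and its reverse complement have the same GC share, so an effect of cytosine as against guanine was not tested. The random sets were drawn unit by unit, whereas several of the 12 units are neighbours, so the 0% overstates the evidence. A shared response to excess light energy stays open. The high light inducible list stood 0.277 higher in high light than in cold (p = 0.000266 with camera, and p = 0.00547 with an estimated correlation), but a smaller change in cold excludes nothing.

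Signal opposite to both flanking genes was above background on all 24 arrays for 35 of the 565 opposite units. That is 6.19%, against 3.45% of the leaders, 2.67% of the units between 2 genes of their strand and 8.2% of the trailers. Passing background on all arrays was thus no rarer there than at leaders, and does not by itself show RNA. The mean log2 level of the 35 units was 11.35, against 9.47 for the other opposite units. On the other strand of these 35 regions, 0 units were above background on all arrays and 15 on none. Base counts allowed for, these strands exceeded those of the other regions by 0.209 (bootstrap interval 0.0704 to 0.351), against 1.16 for the opposite units themselves. The 35 units were picked for their brightness, which inflates the 1.16, so 1 signal from both strands, as residual DNA might give, stays open as part of it. Cytosine made up 39.1% of their probes against 28.0%, and base counts predicted 38.2% of the excess (bootstrap interval 32.5% to 43.7%). Cytosine-rich probes that bind RNA of any sequence could thus account for part of it, and antisense RNA for the rest, which stays open.

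No unit was called in iron depletion. Without the weak iron control array 1 limma called 0 units, and with array weights 0 as well. Both fits give up part of the information from the iron controls, and the normalization still held that array. They therefore cannot exclude it as the cause. In cold there were 58 calls without it, against 36 with it. On arrays simulated with the spread of the real ones, the fit recovered 86.6% of 2-fold changes in iron depletion, which leaves weaker responses and those at few units open. The simulation moved the signal by the full fold at units picked at random. Changes at dim units stay open too, because 680 units were above background on no array. The median SD within the iron groups was 1.01 times that in the cold groups, where 36 units were called. Because the fit uses 1 spread per unit for all groups, this ratio does not bear on the calls, and the spread stays open. A weak response after 12 h, the biological explanation that the design gives, may also be the cause and was not tested.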
